A study of Caenorhabditis elegans with 9 samples.

How the data were processed

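RNA was sequenced from whole Caenorhabditis elegans, per the source label, and the titles add the word embryo without giving the stage at harvest. The 9 libraries fall into 4 groups by genotype, auxin and time: controls at 18 h (n = 2), controls at 24 h (n = 2), hypodermal depletion at 24 h (n = 3) and global depletion at 24 h (n = 2). All strains carried rpoa-2 fused to GFP and a degron, a tag that lets the plant protein TIR1 mark a protein for destruction once the auxin IAA is present. Per the labels' protocols, synchronized eggs were placed on plates with or without 1 mM IAA at 16 °C, RNA was extracted with Trizol, ribosomal RNA was removed with RNase H and libraries were made with a SMARTER kit. TIR1 and IAA were present in the depleted groups and absent from the controls, so their own effects cannot be separated from those of depletion by these samples.

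The table the authors deposited holds whole-number counts per gene over coding sequence, with 1 protein-coding transcript for each gene and no normalization. It lists no count below 3. The row numbers imply 20189 transcripts for each of 10 libraries, so an unlisted count was 0, 1 or 2. The table names 10 libraries, of which 1 matches no sample of the series and was not used here. The coordinates are those of WBcel235, the build named in the submitters' processing notes, which also name DESeq2. The aligner, the counting tool, its use of strand and its treatment of reads shared between genes are not given in the sources used here. Genes with near-identical copies, such as collagens, cysteine proteases, small heat shock proteins and the pud genes, are therefore uncertain one by one, as are overlapping genes. Of 13246 genes listed in at least 1 used library, 13153 identifiers were found in the gene name table, 12467 of them with the same symbol, and 4729 genes were listed in all 9 libraries.

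Library totals ran from 166455 to 2134185 counts, a 12.8-fold range. The control libraries averaged 298851 counts and the depleted libraries 1363414. Before the TMM factors, a count of 3 stood for 15.2 and 18.0 CPM (counts scaled to a total of 1e6) in the 18 h control libraries, 9.25 and 5.92 in the 24 h controls, 1.41, 1.98 and 3.84 in hypodermal depletion and 2.31 and 2.77 in global depletion. These floors cover counting error only. Where all libraries of a group were unlisted, the fold is given as a lower bound, computed with 3 counts in each of those libraries.

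Groups were compared with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr with a minimum count of 10 and a minimum total of 15, a robust quasi-likelihood fit of all 9 libraries with a term per group, and Benjamini-Hochberg adjusted p below 0.05 as the threshold. The filter kept 8026 genes, and the biological coefficient of variation was 0.203. Fold changes are fitted log2 values with a standard error (SE), and CPM values carry the TMM factors. Unlisted counts entered as 1. That value, between 0 and 2, was chosen on simulated data with the real means and library sizes, before any comparison was run: with unlisted counts as 0, an average of 13.3 and 17.1 unchanged genes per simulated set were called against the 18 h controls in global and hypodermal depletion, and with 1 an average of 2.8 and 3. Against the 24 h controls 0 gave fewer false calls, 2.4 and 3.2 per set against 4.9 and 5.7 with 1, and recovered fewer 4-fold changes, 60.6% and 65.1% against 66.2% and 73.8%. Taking them as 2 did about as well as 1: 2.7 and 2.8 false calls against the 18 h controls, and 5.6 and 6.2 against the 24 h controls with 68.3% and 75.6% of 4-fold changes recovered. Against the 24 h controls, over 10 simulated sets of 7674.4 genes on average, 20.1% of 2-fold and 66.2% of 4-fold changes were recovered for global depletion, and 27.5% and 73.8% for hypodermal depletion.

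Gene lists, 41 in all, were fixed from names and textbook knowledge, and 37 with at least 5 tested members were tested as sets with camera from limma 3.58.1 at a preset correlation of 0.01. Camera with an estimated correlation and fry, a rotation test of the list by itself, were run beside it. For each list the members past the threshold were counted over all 8026 genes and adjusted over the list alone. On simulated data a raised list was called in 10 of 10 sets for each depletion and 0 other lists were. The simulated genes were drawn independently of each other. These sets therefore cannot show how many false list calls correlated genes would give.

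The groups, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule names rpoa-2 and the genes whose parts may stand in the TIR1 transgenes (eef-1A.1, col-10, unc-54 and unc-119). Per comparison it adds the 6 genes with the largest rise and the 6 with the largest fall among those past the threshold, with a mean of at least 10 CPM and no overlap between the groups. Histone genes are left out of these. It then takes, for up to 10 called lists with the smallest p, the 3 members past the threshold with the smallest p in the direction of the set and 1 in the other direction, for other lists described 2 members, and up to 6 genes called in opposite directions by the depletions.

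The agreement of both depletions was compared with 100 simulated sets of unchanged groups, because both were set against the same 24 h controls. The developmental position of a library places it on the difference between the controls, 0 at 18 h and 1 at 24 h. Genes with an absolute log2 ratio of at least 1 and at least 10 CPM were chosen in the controls of one replicate number and the position was measured with the controls of the other, then the reverse, and both were averaged. With a true position of 0.5 in simulated data, the mean recovered was 0.532. Positions were compared by an exact permutation test. The alternatives were other scalings, DESeq2 1.42.0, limma-voom, other filters, a minimum fold of 1.5, fits of fewer groups, a replicate term, pooled controls and each library left out in turn. Other values for unlisted counts, a filter on mean CPM, TMM factors from abundant genes, libraries thinned to the shallowest total and a fit without the 18 h controls were added after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.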

Results

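RNA polymerase I transcribes the large ribosomal RNA precursor, and RPOA-2 is one of its core subunits. The series asked what removing RPOA-2 does to gene expression in C. elegans when the protein is depleted globally, with TIR1 under the eft-3 promoter, or in the hypodermis, the epidermis that builds the cuticle, with TIR1 under the col-10 promoter. Coding-sequence counts were held for 9 libraries, with the source given as whole worm. The titles and treatments of all 9 say embryo or embryos, and the protocol puts synchronized eggs on the plates. The labels do not give the stage at harvest, and whether 18 h and 24 h count from plating is not stated. The controls totalled 197970 and 166455 counts at 18 h and 324321 and 506659 at 24 h. The hypodermal libraries totalled 2134185, 1518298 and 781648 counts and the global libraries 1298047 and 1084894. Between 6182 and 11520 genes were listed per library. The depleted libraries were thus deeper than the controls, and changes of weakly expressed genes against the controls were harder to detect than those of abundant genes. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. On 2698 genes, the leading principal component held 46.7% of the variance and the next 17.6%.

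The targeted gene, rpoa-2 (chromosome I, 9280963 to 9286577), is depleted as a protein by the degron, so its mRNA need not fall. Its level was 187 and 272 CPM in the 18 h controls, 156 and 260 CPM in the 24 h controls, 290, 279 and 238 CPM in hypodermal depletion and 355 and 369 CPM in global depletion. The rpoa-2 mRNA rose in global depletion against the 24 h controls (log2 fold change 0.77, SE 0.25, edgeR adjusted p = 0.042), a call that ended when any of 5 single libraries was left out: 18 h control replicate 1 (adjusted p = 0.0619), 24 h control replicate 1 (0.445), hypodermal replicate 2 (0.055), or global replicate 1 (0.173) or 2 (0.205). In hypodermal depletion the rpoa-2 estimate was 0.35 (SE 0.23, adjusted p = 0.471). The mRNA thus does not show which libraries lost the protein. Of the genes whose parts may stand in the transgenes, eef-1A.1 (log2 fold changes -0.26 in global and 0.08 in hypodermal depletion), unc-54 (-0.07 and 0.19) and unc-119 (-0.36 and -0.60) did not pass the test in either depletion. The hypodermal collagen gene col-10 (chromosome V, 9164297 to 9165307) fell in both, from 857 ± 210 CPM (SD, n = 2) in the 24 h controls to 436 ± 88.2 in global (n = 2, log2 fold change -0.97, SE 0.22, adjusted p = 0.00233) and 435 ± 16.3 in hypodermal depletion (n = 3, -0.97, SE 0.20, adjusted p = 0.000911). Without replicate 1 of the 24 h controls neither col-10 call held (adjusted p = 0.117 and 0.112), nor did the global call without global replicate 2 (0.144).

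Global depletion was compared with the 24 h controls to ask what animals with RPOA-2 targeted in most tissues express differently at the same time. Many cuticle collagen genes fell. The collagen genes col-17, dpy-13, dpy-4, dpy-8, col-90 and dpy-5 were listed in both 24 h control libraries, at means from 137 to 204 CPM, and in neither global library, so they were at least 84.2-, 66.7-, 64.9-, 60.5-, 56.5- and 56.4-fold lower (edgeR adjusted p from 6.41e-12 to 6.84e-11). The Kunitz-domain gene mlt-11, needed for molting, fell from 586 ± 50.8 CPM to 9.04 ± 4.27 (SD, n = 2 each, log2 fold change -5.98, SE 0.35, adjusted p = 9.07e-18). In the other direction, pgp-8, a P-glycoprotein-type transporter gene (chromosome X, 10859351 to 10864422), was unlisted in the 24 h controls and reached 362 ± 20.8 CPM, at least 46.5-fold higher (adjusted p = 1.96e-15), and the glutathione transferase gene gst-24 (chromosome II, 13610443 to 13611349) rose from 59.0 ± 6.55 to 997 ± 43.6 CPM (4.09, SE 0.29, adjusted p = 4.59e-15). The other genes with the largest rises were F08G2.5 (5.15, SE 0.52), gadr-6 (at least 9.40-fold), K11H12.4 (at least 9.35-fold), M01G12.9 (4.45, SE 0.51) and ZK1055.7 (4.31, SE 0.37).

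In all, 678 of 8026 genes passed the threshold, 276 higher and 402 lower. With unlisted counts as 0 the split was 286 higher and 250 lower of 536. With the total count as the only scaling it was 363 higher and 342 lower of 705, and the median of all genes moved from 0.01 to 0.11 (log2). Of 64 cuticle collagens, 29 fell, 2 rose and 33 did not pass, and adjusted over the list alone 35 fell and 5 rose (camera adjusted p = 2.09e-21). The collagen gene col-165 was one of those that rose, at least 4.28-fold, though not without replicate 2 of the 24 h controls (adjusted p = 0.0514) or in thinned libraries, and with the controls of both times pooled its estimate turned to -0.40. Of 25 molting enzymes, regulators and apical matrix genes, 11 fell and none rose (13 and 0 over the list alone, adjusted p = 6.70e-20), among them sym-1 (-4.63, SE 0.41) and the zona-pellucida-domain gene noah-2, which fell from a mean of 220 to 12.5 CPM (-4.16, SE 0.38). Of 31 hedgehog-related and patched-related genes 9 fell (10 fell and 1 rose over the list alone, adjusted p = 2.29e-06), with qua-1 at least 18.9-fold and wrt-10 at least 21.5-fold lower and grl-7 at -4.44 (SE 0.68).

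Of 43 ribosome biogenesis factors 14 rose and none fell (23 and 0 over the list alone, camera adjusted p = 3.35e-10). The nucleolar GTPase gene nog-1 went from 551 ± 0.907 to 2067 ± 47.4 CPM (log2 fold change 1.91, SE 0.22, adjusted p = 3.94e-09) and the nucleolar gene pro-2 rose by 1.39 (SE 0.24). Of 6 RNA polymerase I subunits, rpoa-2 included, 3 rose (4 over the list alone), with an adjusted p = 0.00175 for the list and an adjusted p = 0.0686 with an estimated correlation. The 3 that rose, rpoa-2, rpoa-1 and rpac-40, each lost their call without 24 h control replicate 1 (adjusted p = 0.445, 0.146 and 0.117) and without global replicate 1 (0.173, 0.167 and 0.183). The rpac-40 call was also lost without 24 h control replicate 2 (0.229), and those of rpoa-2 (0.205) and rpac-40 (0.121) without global replicate 2. For rpoa-2 it was lost as well without 18 h control replicate 1 (0.0619) or hypodermal replicate 2 (0.055). The ribosomal proteins themselves went lower by a little: of 79 cytosolic ribosomal protein genes 14 fell and 1 rose (16 and 1 over the list alone, adjusted p = 0.00621, adjusted p = 0.668 with an estimated correlation). The list's median of -0.09 became 0.02 with the total count as the only scaling, and its call ended without replicate 1 of the 24 h controls (adjusted p = 0.26). That call also ended with no filter, with pooled controls and with the filter on mean CPM. Among them rps-22 fell by 1.26 (SE 0.23).

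Of 10 genes of the p38 and bZIP immune responses 2 rose (5 over the list alone, adjusted p = 0.000141): C17H12.8 from 26.8 ± 1.94 to 230 ± 1.6 CPM (log2 fold change 3.08, SE 0.36) and irg-4 from 218 ± 2.89 to 823 ± 17.4 CPM (1.92, SE 0.25). Of 10 cytosolic heat shock protein genes 5 rose (6 over the list alone, adjusted p = 3.65e-05), among them the small heat shock genes hsp-16.41 (2.74, SE 0.48) and hsp-16.2 (1.79, SE 0.37). Intestinal markers fell in 9 of 19 cases (11 over the list alone, adjusted p = 8.04e-13, adjusted p = 0.119 with an estimated correlation), led by the cathepsin B-like protease genes cpr-4 (654.9 ± 46 to 86.9 ± 1.31 CPM, -2.91, SE 0.24) and cpr-1 (666 ± 152 to 104.3 ± 14.3 CPM, -2.67, SE 0.26). Of 36 genes of fatty acid oxidation and lipases 14 fell (18 fell and 1 rose over the list alone, adjusted p = 2.06e-07, adjusted p = 0.0572 with an estimated correlation), including the acyl-CoA synthetase gene acs-2 (-4.49, SE 0.49) and the carnitine palmitoyltransferase gene cpt-1 (-1.24, SE 0.23). Of 24 genes of the tricarboxylic acid and glyoxylate cycles 6 fell (8 over the list alone, adjusted p = 2.57e-06, adjusted p = 0.133 with an estimated correlation). Its leading member icl-1, a glyoxylate cycle enzyme, fell from 3379 ± 103 to 748 ± 139 CPM (-2.18, SE 0.22).

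Further lists fell as sets. They were the autophagy and lysosome genes (11 of 44 lower and 1 higher, 18 and 3 over the list alone, adjusted p = 8.24e-05, and adjusted p = 0.222 with an estimated correlation), where the V-ATPase subunit gene vha-13 fell by 1.31 (SE 0.22), and the daf-16 targets and longevity genes (3 of 8, 4 over the list alone, 0.000107, and adjusted p = 0.0652 with an estimated correlation), where icl-1 is again a member. Fatty acid synthesis and desaturation genes fell in 5 of 16 cases (8 lower and 1 higher over the list alone, 0.00262, and adjusted p = 0.192 with an estimated correlation), with the elongase gene elo-1 at -1.45 (SE 0.24). Endoplasmic reticulum unfolded protein response genes fell in 7 of 20 cases and rose in 1 (the same counts over the list alone, 0.00602, and adjusted p = 0.0789 with an estimated correlation), with pdi-2, a protein disulfide isomerase gene, at -1.59 (SE 0.22). Lysozymes and saposin-like genes fell in 4 of 20 cases and rose in 2 (8 and 2 over the list alone, 0.00262, and adjusted p = 0.421 with an estimated correlation): ilys-5 fell by 4.84 (SE 0.43) and lys-2 rose by 2.03 (SE 0.27). The lysozyme call ended under the filter on mean CPM and in thinned libraries, and the fatty acid synthesis call with pooled controls. The pharynx markers (2 of 20 lower, also over the list alone, 0.049, and adjusted p = 0.48 with an estimated correlation) lost their call under 2 other scalings (0.0559 and 0.0502) and without any of 5 single libraries, at adjusted p from 0.0521 to 0.192 (18 h control replicate 2, either 24 h control, hypodermal replicate 3 or global replicate 2). The pharynx call was lost as well with no filter, in a fit of these groups by themselves, with unlisted counts as 0, under the filter on mean CPM and in thinned libraries. By fry the ribosomal protein (adjusted p = 0.3), lysozyme (0.0851) and pharynx (0.145) lists did not pass. With an estimated correlation, 6 of the 17 called lists kept their call: collagens, molting genes, hedgehog-related genes, ribosome biogenesis factors, heat shock proteins and the p38 and bZIP immune genes. Some lay near the threshold. Over the alternatives the adjusted p of the list reached 0.0219 for collagens and 0.0408 for molting genes. It reached 0.0485 for ribosome biogenesis factors, for heat shock proteins and for the immune genes. The count of 678 genes dropped to 415 without replicate 1 of the 24 h controls, 392 without global replicate 1 and 348 without global replicate 2. Median, mean and test had 1 sign in each list called in any of the 6 comparisons.

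**Figure D1:**
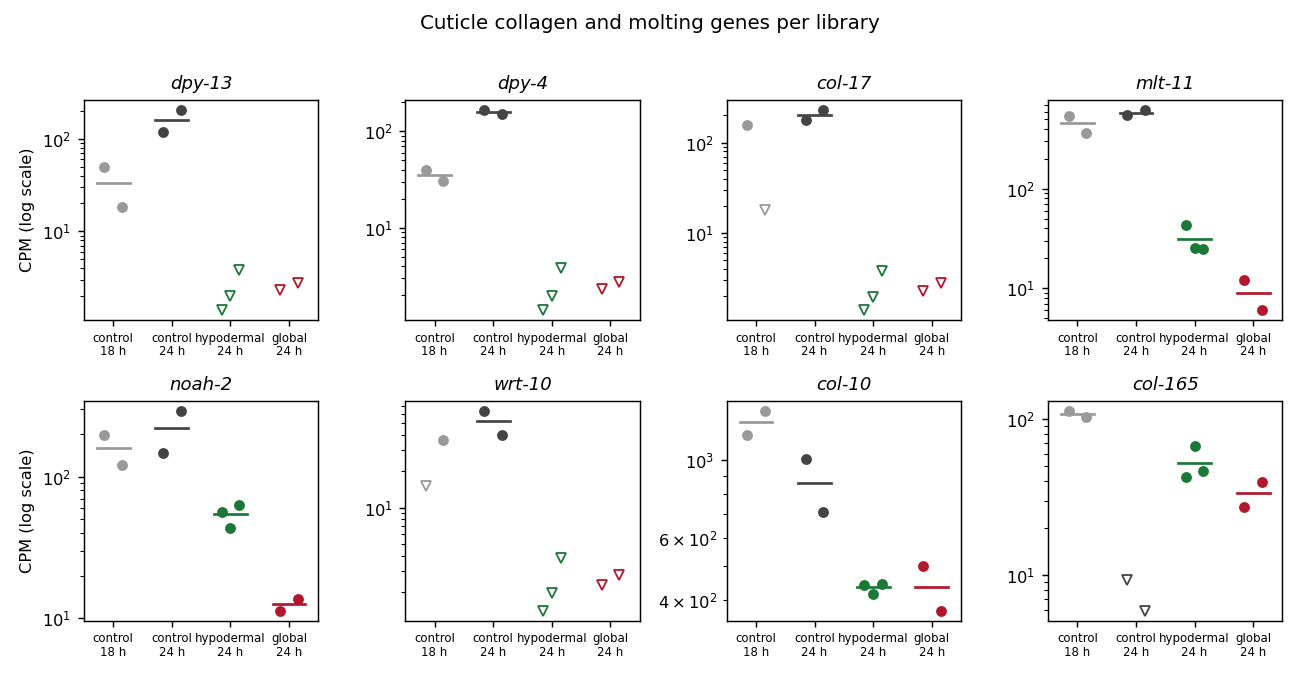
Level (CPM, log axis) of 8 cuticle and molting genes in each of the 9 libraries of the 4 groups; filled circles are listed counts, open triangles mark the CPM of 3 counts where a library was unlisted, and lines are group means where each library was listed. The genes dpy-13, dpy-4, col-17 and wrt-10 are unlisted in all 5 depleted libraries, mlt-11 lies at 31.1 (hypodermal) and 9.04 CPM (global) against 586 in the 24 h controls, and col-165 is unlisted in both 24 h controls.

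Hypodermal depletion was compared with the same 24 h controls to ask what follows when TIR1 is made in the hypodermis. Again cuticle collagens were among the largest falls. None of col-17, dpy-13, dpy-4, dpy-8, col-90 and dpy-5 was listed in the 3 hypodermal libraries, which put them at least 83.3-, 66.0-, 64.3-, 59.9-, 55.9- and 55.8-fold below the 24 h controls (edgeR adjusted p from 2.42e-14 to 3.33e-13). The molting gene mlt-11 fell to 31.1 ± 10.6 CPM (SD, n = 3, log2 fold change -4.17, SE 0.26, adjusted p = 5.34e-17). Among the largest rises, pud-3 (chromosome V, 2324510 to 2326827), unlisted in the 24 h controls, reached 387 ± 91.1 CPM, at least 49.7-fold higher (adjusted p = 4.62e-15). Its neighbour pud-4 (chromosome V, 2326678 to 2327262) overlaps it, so how reads were shared between them is uncertain. It rose by 4.40 (SE 0.55) to 106 ± 3.42 CPM. The transporter gene pgp-8 was at least 21.5-fold, zig-4 at least 13-fold, gadr-6 at least 8.10-fold and col-165 at least 6.67-fold higher, the last not with pooled controls or in thinned libraries.

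In all, 405 genes passed, 133 higher and 272 lower. With unlisted counts as 0 the split was 116 higher and 134 lower of 250. Of 64 cuticle collagens 33 fell and 3 rose (37 and 5 over the list alone, camera adjusted p = 4.90e-44), and the collagen gene sqt-1 fell by 6.57 (SE 0.49). Of 25 molting and apical matrix genes 9 fell and 1 rose (10 and 1 over the list alone, adjusted p = 6.67e-12, adjusted p = 0.06 with an estimated correlation). They included lin-42, the worm homologue of the period clock gene (-3.40, SE 0.36), and lpr-3, a lipocalin-related gene of the apical matrix (-4.89, SE 0.56). Of 31 hedgehog-related and patched-related genes 9 fell (14 over the list alone, adjusted p = 1.90e-08), with wrt-10 at least 21.2-fold lower, grl-7 at -3.87 (SE 0.56) and grd-10 at -1.96 (SE 0.32). In both depletions the hedgehog-related call was lost once the libraries were thinned to the shallowest total (adjusted p = 0.123 in hypodermal and up to 0.174 in global depletion), and in global depletion also under the filter on mean CPM.

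Markers of the hypodermis itself did not move as a set in either depletion: 0 of 13 junction and regulator genes passed in hypodermal depletion (0 also over the list alone, camera adjusted p = 0.889), and 2 fell in global depletion (2 over the list alone, adjusted p = 0.361). Outside the cuticle, icl-1 fell by 2.23 (SE 0.19) to 721 ± 65.7 CPM, acs-2 changed by -4.645 (SE 0.43) and cpt-1 by -1.45 (SE 0.20), close to their values in global depletion. Of 36 fatty acid oxidation genes 3 fell and 1 rose (3 and 2 over the list alone, adjusted p = 0.434 for the list). Cytochrome P450 genes rose as a set (4 of 34 higher and 1 lower, 6 and 1 over the list alone, 0.00232, and adjusted p = 0.417 with an estimated correlation), a call lost without replicate 2 of the 24 h controls (0.0979). Autophagy and lysosome genes fell as a set (4 of 44, 5 lower and 1 higher over the list alone, 0.00611, and adjusted p = 0.515 with an estimated correlation), led by epg-9 (-1.59, SE 0.33). So did tricarboxylic acid and glyoxylate cycle genes (1 of 24, icl-1, also over the list alone, 0.0107, and adjusted p = 0.515 with an estimated correlation). Both calls ended without replicate 1 of the 24 h controls (0.259 and 0.154) and with no filter, the tricarboxylic acid call also with pooled controls. The P450 call ended with no filter too. Pharynx markers fell in 1 of 20 cases (3 over the list alone, 0.0284, and adjusted p = 0.515 with an estimated correlation), a call lost without 18 h control replicate 2 (0.0587), 24 h control replicate 1 (0.197) or hypodermal replicate 3 (0.125). In all, 11 of 25 alternatives ended the pharynx call, among them no filter, the filter at 5 CPM, a fit of these groups by themselves, the filter on mean CPM and thinned libraries. By fry the P450 (0.0518), autophagy (0.12), tricarboxylic acid (0.104) and pharynx (0.155) lists did not pass.

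Of 43 ribosome biogenesis factors 1 rose, nog-1, to 1109 ± 50.1 CPM (log2 fold change 1.01, SE 0.20, 1 over the list alone). The list's call (adjusted p = 0.0412, adjusted p = 0.515 with an estimated correlation) ended under RLE scaling (0.0526) and without any of 5 single libraries: either 18 h control (0.0643 and 0.0502), 24 h control replicate 1 (0.291), hypodermal replicate 2 (0.174) or global replicate 1 (0.054). It also ended in a fit of these groups by themselves, in a fit without the 18 h controls, under the filter on mean CPM, in thinned libraries and by fry (0.115). None of the 6 RNA polymerase I subunits passed (0 also over the list alone, adjusted p = 0.0776). Of 79 cytosolic ribosomal protein genes 1 rose and 1 fell (1 and 0 over the list alone, adjusted p = 0.344). The collagen and hedgehog-related lists kept their call with an estimated correlation, and the other 6 lists called did not. The count of 405 dropped to 244 without replicate 1 and 251 without replicate 2 of the 24 h controls, and to 258 without hypodermal replicate 2.

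Both depletions were set against the same controls, so their agreement has to be read against that of unchanged groups. Across the 8026 genes, which are not independent replicates, the log2 fold changes had a correlation of 0.76, against a mean of 0.702 (0.687 to 0.717) in 100 simulated sets of unchanged groups, and a covariance of 0.663 against 0.228, a difference of 0.435. They had the same sign for 78.0% of genes (73.0% simulated). The simulated sets left out the 18 h controls and were filtered and fitted anew, with a spread that followed the trend over expression. The real data without those controls gave 8522 genes to test. The simulated values thus come from another fit and other genes, and small gaps to them cannot be read as agreement. In both depletions 81 genes were called higher and 151 lower, where independent lists of these sizes would share 4.57 and 13.6, and 8 were called in opposite directions. The shared calls, the falls above all, depended on the unlisted counts: taken as 0, 78 genes were higher and 77 lower in both. Taken as 2, 89 were higher and 161 lower. In libraries thinned to the shallowest total, where 3635 genes could be tested, 29 were higher and 69 lower in both. The 2 control libraries are too few to split into groups of 2, so part of the excess may come from the shared controls. With hypodermal depletion set against the 18 h controls instead, which shares no library, the correlation was 0.316, the covariance 0.352 and the share with the same sign 59.9%. In that case 100 genes were called higher in both, 116 lower in both and 28 in opposite directions. Genes called in both included gst-24, pgp-8 and col-165 among those that rose, and mlt-11, grl-7, acs-2 and icl-1 among those that fell.

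**Figure D2:**
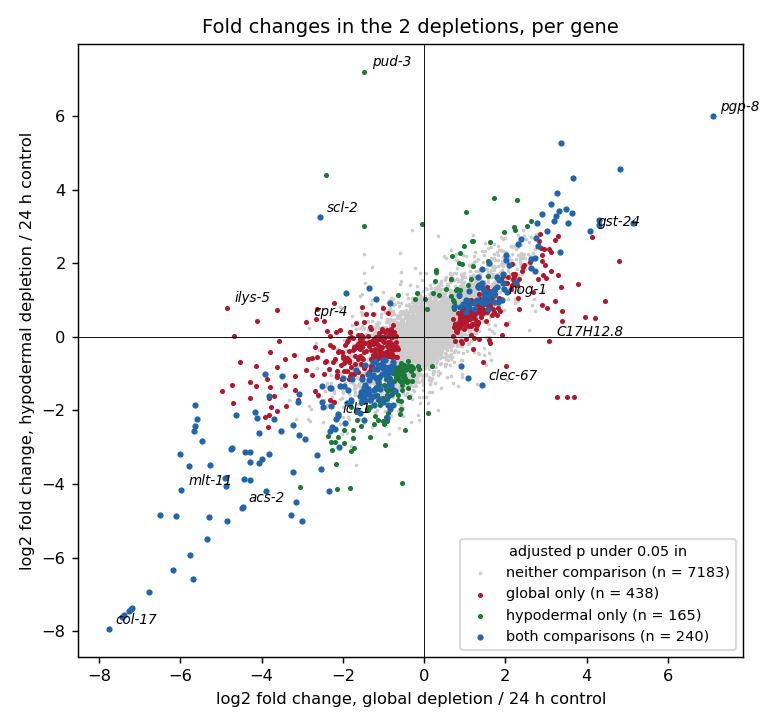
Fitted log2 fold change against the 24 h controls of each of 8026 genes in global depletion (x axis) and hypodermal depletion (y axis); each point is a gene, coloured by whether it was called in neither comparison, 1 of them or both. In all, 240 genes were called in both, 438 in global depletion alone and 7183 in neither.

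The depletions were then compared with each other, both with TIR1 and IAA and at the same time, to find what differs when the driver does. The gene dct-17 was at 56.1 ± 4.14 CPM in hypodermal depletion (SD, n = 3) and 714 ± 49.8 in global depletion (n = 2; log2 ratio of hypodermal over global -3.68, SE 0.22, edgeR adjusted p = 1.69e-17). The immune gene C17H12.8 was at 25.3 ± 2.40 against 230 ± 1.6 CPM (-3.19, SE 0.27, adjusted p = 6.82e-13). In the other direction cpr-4 was at 873 ± 150 against 86.9 ± 1.31 CPM (3.33, SE 0.23), cpr-1 at 928 ± 179 against 104.3 ± 14.3 CPM (3.15, SE 0.24) and the invertebrate-type lysozyme gene ilys-5 at 247 ± 38.1 against 4.95 ± 2.74 CPM (5.63, SE 0.38). The genes pud-3 and pud-4, unlisted in both global libraries, were at least 160.0- and 43.9-fold higher in hypodermal depletion. Also among the largest differences, scl-2 (5.83, SE 0.45) and alh-13 (4.73, SE 0.57) were higher in hypodermal depletion, as was clec-170 (at least 9.45-fold), and M01G12.9 (-3.48, SE 0.32), ZK938.3 (-3.42, SE 0.52), gst-38 (-2.95, SE 0.43) and clec-265 (-2.81, SE 0.30) were lower.

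In all, 355 genes passed, 240 higher in hypodermal depletion and 115 lower. With the total count as the only scaling the split was 205 higher and 157 lower of 362. Of 10 p38 and bZIP immune genes 6 were lower in hypodermal depletion (7 over the list alone, camera adjusted p = 6.83e-14), with irg-4 at -1.88 (SE 0.20) and T24B8.5 at -3.22 (SE 0.64). Of 20 lysozyme and saposin-like genes 9 were higher and 1 lower (13 and 1 over the list alone, 1.95e-08, and adjusted p = 0.141 with an estimated correlation), the exception being lys-2 (-1.69, SE 0.21). Of 19 intestinal markers 8 were higher and 1 lower (9 and 2 over the list alone, 9.16e-12, and adjusted p = 0.154 with an estimated correlation), and of 36 fatty acid oxidation genes 9 were higher (15 higher and 1 lower over the list alone, 5.56e-10, and adjusted p = 0.0516 with an estimated correlation), such as acox-1.4 (3.14, SE 0.49) and dhs-28 (1.56, SE 0.25).

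Ribosome biogenesis factors were lower in hypodermal depletion in 3 of 43 cases (6 over the list alone, camera adjusted p = 3.38e-09, and adjusted p = 0.0559 with an estimated correlation), with nog-1 at -0.90 (SE 0.18). Cytosolic ribosomal proteins were higher in 5 of 79 (7 over the list alone, 9.30e-07, and adjusted p = 0.516 with an estimated correlation). Molting and apical matrix genes were higher in hypodermal depletion in 6 of 25 cases (9 over the list alone, 3.57e-08, and adjusted p = 0.127 with an estimated correlation), with sym-1 at 2.52 (SE 0.40) and the fibrillin-like gene fbn-1 at 2.44 (SE 0.35). Of 64 collagens 3 were higher and 8 lower (5 and 8 over the list alone, adjusted p = 0.259), and the list's mean of 0.07 and median of -0.17 differ in sign; col-160 was lower by 1.14 (log2 ratio -1.14, SE 0.20). Heat shock protein genes were lower in 3 of 10 cases (6 over the list alone, 4.29e-06, and adjusted p = 0.0516 with an estimated correlation). Endoplasmic reticulum unfolded protein response genes were higher in 7 of 20 and lower in 1 (9 and 1 over the list alone, 3.88e-05, and adjusted p = 0.0516 with an estimated correlation): pdi-2 (1.43, SE 0.20) and enpl-1 (1.17, SE 0.20) were higher.

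Fatty acid synthesis genes were higher in 3 of 16 cases (6 over the list alone, 3.88e-05, and adjusted p = 0.141 with an estimated correlation), led by the elongase gene elo-6 (2.33, SE 0.27), and daf-16 targets in 3 of 8 (4 over the list alone, 0.00263, and adjusted p = 0.141 with an estimated correlation), led by the catalase gene ctl-2 (1.59, SE 0.29). The molting and daf-16 calls, and those of ctl-2 and alh-13, ended in thinned libraries, and that of T24B8.5 with unlisted counts as 0. The tricarboxylic acid list was higher with 0 of 24 members past the threshold (0 over the list alone, 0.00278, and adjusted p = 0.379 with an estimated correlation). Body wall muscle markers were higher in 2 of 21 cases (5 over the list alone, 0.0179, and adjusted p = 0.379 with an estimated correlation), which did not hold without hypodermal replicate 1 (0.0519) or 2 (0.0689). The remaining 3 lists called, lower in hypodermal depletion, were the neuropeptides (0 of 51, also over the list alone, 0.0388, and adjusted p = 0.395 with an estimated correlation), the neuronal markers (1 of 22, also over the list alone, 0.0432, and adjusted p = 0.395 with an estimated correlation) and the RNA polymerase I subunits (0 of 6, also over the list alone, 0.047, and adjusted p = 0.312 with an estimated correlation). The neuropeptide call ended with the total count as the only scaling (0.0509) and without hypodermal replicate 1 (0.0847) or global replicate 2 (0.0611), the polymerase call without hypodermal replicate 1 (0.0626) or 2 (0.0732) or global replicate 2 (0.126), and the neuronal call without any of 18 h control replicate 2, 24 h control replicate 1, hypodermal replicate 3 or either global library (0.0504 to 0.24). In all, 12 of 24 alternatives ended the neuronal call, among them the filter at 5 CPM, a fit of these groups by themselves, the filter on mean CPM and thinned libraries, and the last 2 ended the neuropeptide call too. By fry the polymerase (0.0519), ribosomal protein (0.176), neuropeptide (0.177) and neuronal (0.15) lists did not pass. With an estimated correlation the p38 and bZIP immune genes alone kept their call of the 16. Without global replicate 1 or 2 the count of 355 dropped to 156 and 161.

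**Figure D3:**
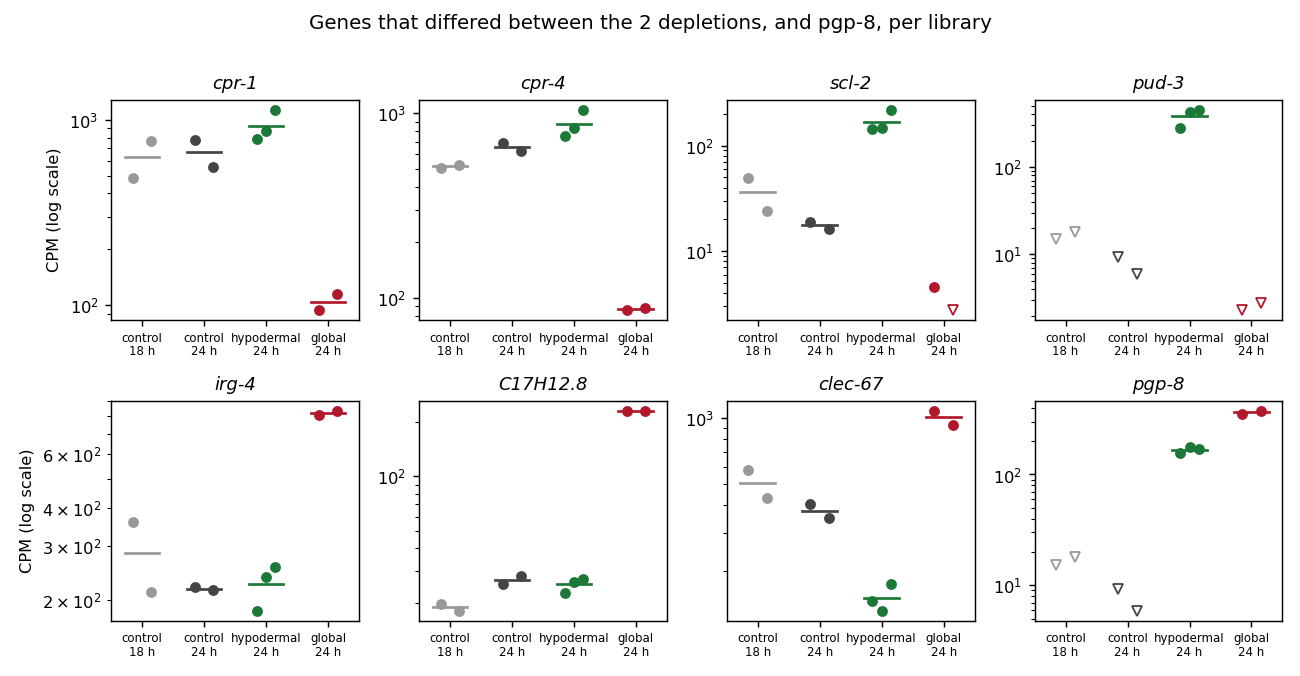
Level (CPM, log axis) in each of the 9 libraries of pgp-8 and of genes that differed between the depletions, 8 genes in all. Filled circles are listed counts, open triangles mark the CPM of 3 counts where a library was unlisted, and lines are group means where each library was listed. Mean cpr-4 was 873 CPM in hypodermal and 86.9 in global depletion, mean irg-4 was 226 and 823 CPM, and pud-3 was listed in the 3 hypodermal libraries alone.

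The controls at 24 h and 18 h show what 6 more hours change without depletion. Collagen genes went both ways. The genes col-165 and col-65 were unlisted at 24 h and at least 13.9- and 9.23-fold lower than at 18 h (edgeR adjusted p = 2.51e-06 and 0.000523), and col-130 fell by 5.04 (SE 0.69). The collagen genes col-125 (log2 fold change -2.67, SE 0.28) and col-39 (-2.01, SE 0.24) fell as well, while the counts in 64 collagens were 5 higher and 14 lower (15 and 20 over the list alone, camera adjusted p = 0.18). The antimicrobial saposin-like gene spp-17 rose by 1.78 (SE 0.30), and cpr-5 rose from 243 ± 50.3 to 708 ± 155 CPM (1.55, SE 0.27, n = 2 each). The pharyngeal gland genes phat-5 (-2.66, SE 0.40) and phat-4 (-2.83, SE 0.46) and the neuropeptide gene nlp-24 (-2.74, SE 0.36) fell. The largest rises, in F55F3.2, Y6B3B.9, hcp-2, F17C11.11, B0205.6 and nasp-1, were bounds of 2.63- to 3.5-fold, and each lost its call without 18 h control replicate 1 (adjusted p from 0.115 to 0.202), without 18 h control replicate 2 (0.0897 to 0.151) and without at least 1 of the 24 h controls (0.0504 to 0.176).

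In all, 246 genes passed, 75 higher and 171 lower at 24 h. With unlisted counts as 0 the split turned to 210 higher and 100 lower of 310. The test of lists was camera, and none of its 10 calls here held with an estimated correlation. Translation factors and tRNA synthetases were higher as a set, with 1 higher and 1 lower in 68 cases (1 and 1 over the list alone, adjusted p = 2.61e-07, and adjusted p = 0.328 with an estimated correlation). Cytosolic ribosomal proteins were higher with 0 past the threshold in 79 cases (0 over the list alone, adjusted p = 3.68e-06, and adjusted p = 0.599 with an estimated correlation). Ribosome biogenesis factors rose in 2 of 43 cases (2 over the list alone, adjusted p = 0.000146, and adjusted p = 0.328 with an estimated correlation). Fatty acid synthesis genes were higher as a set with none past the threshold in 16 cases (9 over the list alone, adjusted p = 0.000146, and adjusted p = 0.328 with an estimated correlation). DNA replication and cell cycle genes rose in 1 of 42 cases (3 over the list alone, adjusted p = 0.000185, and adjusted p = 0.328 with an estimated correlation). Histone genes rose in 2 of 25 cases (2 over the list alone, adjusted p = 0.00204, and adjusted p = 0.599 with an estimated correlation). Body wall muscle markers fell in 1 of 21 cases (3 over the list alone, adjusted p = 0.000468, and adjusted p = 0.45 with an estimated correlation). Autophagy and lysosome genes fell in 3 of 44 cases (4 over the list alone, adjusted p = 0.00169, and adjusted p = 0.599 with an estimated correlation). Pharynx markers fell in 2 of 20 cases (2 over the list alone, adjusted p = 0.0247, and adjusted p = 0.599 with an estimated correlation). Hedgehog-related genes fell in 5 of 31 cases (5 over the list alone, adjusted p = 0.0337, and adjusted p = 0.45 with an estimated correlation). Among them grl-21 (-3.03, SE 0.52) and grl-4 (-1.62, SE 0.30) fell.

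The muscle call ended without 18 h control replicate 2 (0.079), the autophagy call without 18 h control replicate 2 (0.079) or 24 h control replicate 2 (0.208), the pharynx call without 18 h control replicate 1 (0.255) or 24 h control replicate 2 (0.0882), and the hedgehog-related call without 18 h control replicate 1 (0.219), either 24 h control (0.147 and 0.0882) or either global library (0.0523 and 0.0554). With no filter all 4 of these calls ended. Unlisted counts as 0 ended the pharynx and hedgehog-related calls, and the filter at 5 CPM the hedgehog-related call. By fry none of the 10 lists passed (adjusted p from 0.0702 to 0.292). The count of 246 dropped to 142 and 127 without 18 h control replicate 1 or 2, and to 161 and 76 without 24 h control replicate 1 or 2.

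Global depletion was also set against the earlier controls at 18 h, to see whether depleted animals resembled younger animals. Many collagen and molting genes lay below the 18 h level too. The mlt-11 mRNA was lower than at 18 h (log2 fold change -5.62, SE 0.36, edgeR adjusted p = 1.96e-16, n = 2 each), as were col-125 (-4.13, SE 0.29) and col-39 (-2.41, SE 0.24). Unlisted in global depletion, dpy-8, mlt-10, dpy-5, col-149 and lpr-5 were at least 30.4-, 25.7-, 24.6-, 24.9- and 21.4-fold lower, and col-17 at least 33.8-fold, the last not without 18 h control replicate 1 (adjusted p = 0.505). The gst-24 mRNA was higher by 6.18 (SE 0.42), lem-2, an inner nuclear membrane protein gene, by 4.31 (SE 0.52), and pgp-8, M01G12.9, F08G2.5 and F55F3.2 at least 22-, 12-, 10.9- and 6.62-fold. Of 1172 genes past the threshold 481 were higher and 691 lower. The split depends on unlisted counts in the shallow 18 h controls: taken as 0 it was 898 higher and 341 lower of 1239. RLE scaling moved the median of all genes from -0.02 to -0.11 (log2).

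Of 64 collagens 37 were lower and 3 higher than at 18 h (39 and 3 over the list alone, camera adjusted p = 3.18e-21). The collagen gene col-42 was among those higher (1.84, SE 0.26). Of 43 ribosome biogenesis factors 23 were higher (27 over the list alone, adjusted p = 2.10e-16), with nog-1 at 2.11 (SE 0.23), K07H8.10 at 1.96 (SE 0.25) and pro-2 at 1.91 (SE 0.28). These 2 calls of 16 held with an estimated correlation. Over the alternatives the adjusted p of the list reached 0.0201 for collagens and 0.0492 for ribosome biogenesis factors. Molting genes were lower in 12 of 25 cases (13 lower and 1 higher over the list alone, adjusted p = 8.33e-13, and adjusted p = 0.0663 with an estimated correlation). Autophagy and lysosome genes were lower in 22 of 44 cases (25 lower and 2 higher over the list alone, adjusted p = 2.01e-09, and adjusted p = 0.0957 with an estimated correlation). The ubiquitin-like autophagy gene lgg-1 fell by 1.92 (SE 0.26). Hedgehog-related genes were lower in 14 and higher in 1 of 31 cases (18 lower and 1 higher over the list alone, adjusted p = 4.25e-09, and adjusted p = 0.0543 with an estimated correlation). Intestinal markers were lower in 9 of 19 cases (12 lower and 1 higher over the list alone, adjusted p = 1.88e-08, and adjusted p = 0.187 with an estimated correlation). Fatty acid oxidation genes were lower in 13 and higher in 3 of 36 cases (16 lower and 3 higher over the list alone, adjusted p = 1.20e-07, and adjusted p = 0.0663 with an estimated correlation). Body wall muscle markers were lower in 11 of 21 cases (12 over the list alone, adjusted p = 1.49e-05, and adjusted p = 0.15 with an estimated correlation). The daf-16 targets were lower in 4 of 8 cases (4 over the list alone, adjusted p = 2.14e-05, and adjusted p = 0.0664 with an estimated correlation). Pharynx markers were lower in 7 of 20 cases (9 over the list alone, adjusted p = 0.000196, and adjusted p = 0.186 with an estimated correlation). Glycolysis and gluconeogenesis genes were lower in 6 of 19 cases (6 over the list alone, adjusted p = 0.00214, and adjusted p = 0.158 with an estimated correlation). Tricarboxylic acid and glyoxylate cycle genes were lower in 4 of 24 cases (6 over the list alone, adjusted p = 0.0141, and adjusted p = 0.393 with an estimated correlation).

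Translation factors and tRNA synthetases were higher in 17 and lower in 1 of 68 cases (23 and 1 over the list alone, adjusted p = 1.75e-07, and adjusted p = 0.0781 with an estimated correlation). Among them were eif-2A (1.68, SE 0.29) and the leucyl-tRNA synthetase gene lars-1 (1.18, SE 0.24). Heat shock protein genes were higher in 5 of 10 cases (6 over the list alone, adjusted p = 6.26e-05, and adjusted p = 0.0663 with an estimated correlation). RNA polymerase I subunits were higher in 1 of 6 cases (3 over the list alone, adjusted p = 0.0129, and adjusted p = 0.169 with an estimated correlation). The subunit gene that passed was rpoa-1 (1.19, SE 0.26). DNA replication genes were higher in 1 of 42 cases (0 over the list alone, adjusted p = 0.0223, and adjusted p = 0.323 with an estimated correlation). The replication call ended without 18 h control replicate 1 (0.114), under the filter on mean CPM and by fry (0.0542), and the tricarboxylic acid call without 18 h control replicate 2 (0.0688) or global replicate 2 (0.115). With no filter the direction of the tricarboxylic acid list turned (adjusted p = 0.705) and the body wall muscle and glycolysis calls ended. The tricarboxylic acid call also ended with unlisted counts as 2. The count of 1172 dropped to 657 and 752 without 18 h control replicate 1 or 2, and to 756 and 688 without global replicate 1 or 2.

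In hypodermal depletion, set against the 18 h controls, many collagen genes were lower as well. The collagen genes col-125 (log2 fold change -4.38, SE 0.25, edgeR adjusted p = 4.60e-18, n = 3 against 2), col-39 (-3.40, SE 0.22) and col-107 (-3.28, SE 0.23) were lower than at 18 h, as were dpy-8, dpy-5 and col-90 by at least 30-, 24.3- and 17.5-fold, F49F1.7 and W02H5.16 by at least 21.8- and 16.7-fold, and col-17 by at least 33.5-fold, the last not without 18 h control replicate 1 (adjusted p = 0.465). Higher were pud-3 (at least 23.5-fold), pgp-8 (at least 10.2-fold), pud-4 (at least 6.46-fold), vrk-1 (at least 4.34-fold), gst-24 (4.96, SE 0.43) and lem-2 (3.72, SE 0.53). Of 1046 genes past the threshold 438 were higher and 608 lower. RLE scaling gave 317 higher and 734 lower of 1051, and unlisted counts as 0 gave 970 higher and 291 lower of 1261.

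Of 64 collagens 36 were lower and 1 higher (43 and 3 over the list alone, camera adjusted p = 9.50e-33). Of 31 hedgehog-related genes 16 were lower and 1 higher (17 and 2 over the list alone, adjusted p = 2.72e-10), with grd-13 at -3.67 (SE 0.40). These 2 calls of 14 held with an estimated correlation. Over the alternatives the adjusted p of the list reached 0.00391 for collagens and 0.0308 for hedgehog-related genes. Translation factors were higher in 20 and lower in 1 of 68 cases (24 and 1 over the list alone, adjusted p = 1.60e-08, and adjusted p = 0.147 with an estimated correlation). The aspartyl-tRNA synthetase gene dars-1 rose by 1.73 (SE 0.35). Ribosome biogenesis factors were higher in 12 of 43 cases (14 over the list alone, adjusted p = 3.94e-07, and adjusted p = 0.165 with an estimated correlation). Among them K07H8.10 rose by 1.48 (SE 0.23). Cytosolic ribosomal proteins were higher in 11 of 79 cases (12 over the list alone, adjusted p = 1.18e-06, and adjusted p = 0.476 with an estimated correlation). The paralog rpl-11.1 rose by 2.48 (SE 0.45). Fatty acid synthesis genes were higher in 4 of 16 cases (5 over the list alone, adjusted p = 0.00273, and adjusted p = 0.255 with an estimated correlation). The gene acs-1 rose by 2.46 (SE 0.40). Lysozymes and saposin-like genes were higher in 3 of 20 cases (3 over the list alone, adjusted p = 0.0147, and adjusted p = 0.452 with an estimated correlation). The gene spp-17 rose by 2.54 (SE 0.28). DNA replication genes were higher in 2 of 42 cases (0 over the list alone, adjusted p = 0.0489, and adjusted p = 0.449 with an estimated correlation).

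Autophagy and lysosome genes were lower in 15 and higher in 1 of 44 cases (16 and 1 over the list alone, adjusted p = 2.52e-07, and adjusted p = 0.223 with an estimated correlation). The lgg-1 mRNA fell by 2.01 (SE 0.23). Molting genes were lower in 9 of 25 cases (10 over the list alone, adjusted p = 1.32e-05, and adjusted p = 0.223 with an estimated correlation). Among them mlt-11 fell by 3.82 (SE 0.27). Pharynx markers were lower in 9 of 20 cases (10 lower and 1 higher over the list alone, adjusted p = 2.93e-05, and adjusted p = 0.223 with an estimated correlation). The gland gene phat-5 fell by 3.47 (SE 0.33). The daf-16 targets were lower in 3 of 8 cases (4 lower and 1 higher over the list alone, adjusted p = 0.00696, and adjusted p = 0.255 with an estimated correlation). Body wall muscle markers were lower in 6 of 21 cases (7 over the list alone, adjusted p = 0.00696, and adjusted p = 0.404 with an estimated correlation). Neuronal markers were lower in 1 and higher in 1 of 22 cases (1 and 1 over the list alone, adjusted p = 0.0489, and adjusted p = 0.45 with an estimated correlation). Single libraries ended 5 of these calls. Without 18 h control replicate 1 the replication (0.185), daf-16 (0.109) and neuronal (0.335) calls were lost. Without 18 h control replicate 2 the muscle call (0.155) was lost, and without hypodermal replicate 2 the replication call (0.0554). Without hypodermal replicate 3 the replication (0.0623), lysozyme (0.0623) and neuronal (0.124) calls were lost, and without either 24 h control or either global library the neuronal call (0.0584 to 0.0714). With no filter the direction of the muscle list turned (0.752) and the daf-16 and neuronal calls ended. Unlisted counts as 2 ended the muscle call. The replication and neuronal calls ended in 10 and 16 of 23 alternatives, both of them with unlisted counts as 0 or 2, under the filter on mean CPM and in thinned libraries, and the neuronal call also under the filter at 5 CPM and in a fit of these groups by themselves. By fry the ribosomal protein (0.127), replication (0.0716), lysozyme (0.127) and neuronal (0.0582) lists did not pass. The count of 1046 dropped to 507 and 634 without 18 h control replicate 1 or 2.

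**Figure D4:**
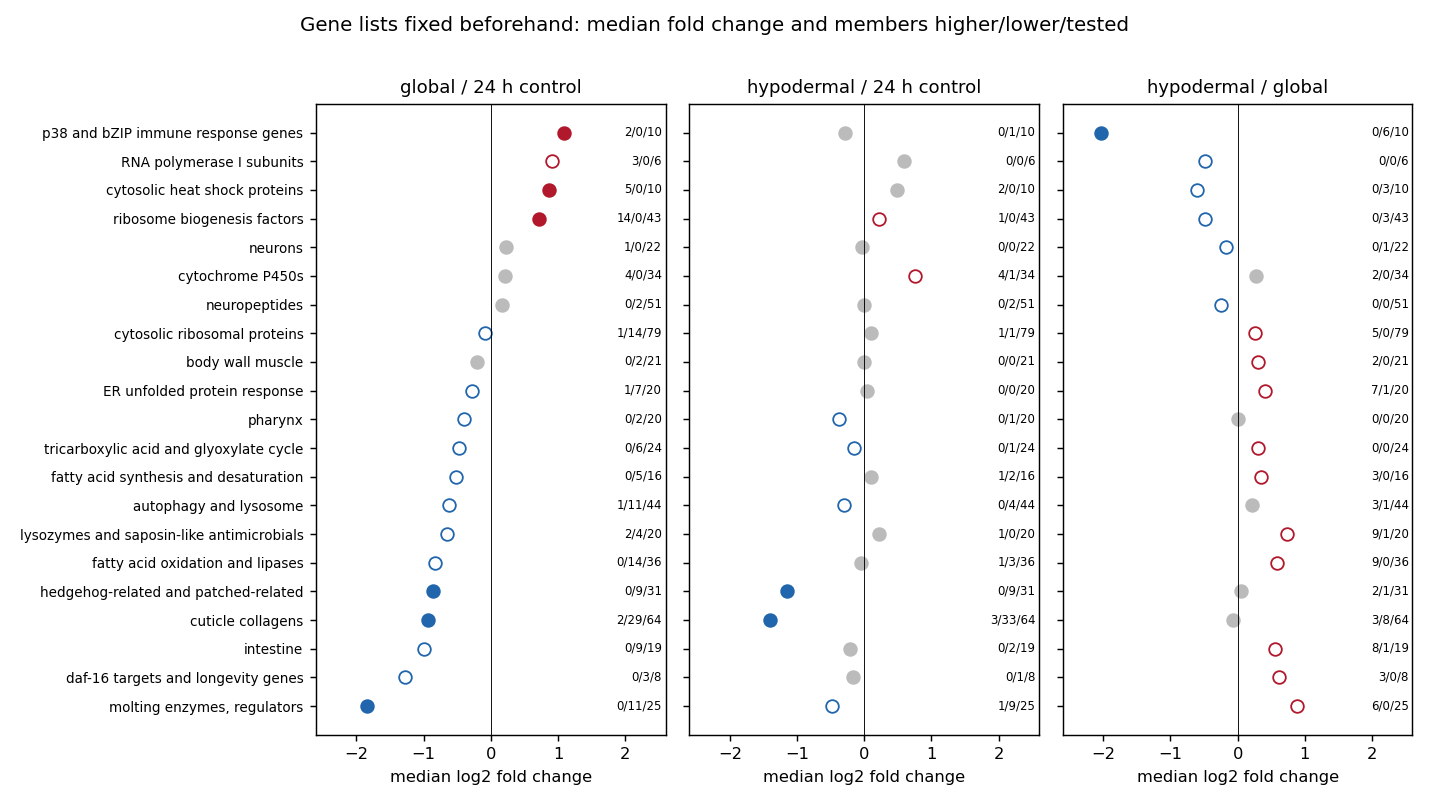
Median log2 fold change, with unlisted genes at their bounds, of the 21 gene lists called in at least 1 of the comparisons of global depletion with the 24 h controls, hypodermal depletion with the 24 h controls and hypodermal with global depletion; red is called higher, blue called lower and grey not called, filled symbols kept their call with an estimated correlation (grey symbols are filled as well), and the numbers are members higher, lower and tested. Cuticle collagens lie at -0.94 and -1.40 in global and hypodermal depletion, and ribosome biogenesis factors at 0.72 in global depletion.

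The developmental position asked where the depleted libraries lie on the change from the 18 h to the 24 h controls. On 2777 and 2847 genes, of which 59.1% and 60% moved the same way in the other pair of controls, the hypodermal libraries lay at 1.04, 1.05 and 1.00 (mean 1.03 ± 0.03, SD, n = 3) and the global libraries at 0.94 and 0.92 (0.928 ± 0.019, n = 2), where 0 is the 18 h and 1 the 24 h control. Each position averages 2 estimates, and these lay apart. With genes chosen in the replicate 1 controls, the hypodermal libraries lay at 1.112, 1.192 and 1.138 and the global libraries at 1.054 and 1.046. With genes chosen in the replicate 2 controls they lay at 0.969, 0.915 and 0.854 and at 0.828 and 0.784. The SDs do not cover this gap. The difference of 0.102 between the depletions had an exact 2-sided permutation p of 0.1, the smallest that 10 arrangements allow.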

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

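A difference between the depletions is what singled out each result here: both groups had TIR1 and IAA at the same time, and 355 genes and 16 gene lists passed the test between them. With an estimated correlation 1 of the 16 lists kept its call. Genes called in opposite directions against the 24 h controls were taken one by one. The C-type lectin gene clec-67 rose in global depletion (log2 fold change 1.42) and fell in hypodermal depletion (-1.32), a log2 ratio of hypodermal over global depletion of -2.74 (SE 0.20, edgeR adjusted p = 1.46e-14). Its relative clec-52 went the same ways (1.07 and -1.12), a ratio of -2.19 (SE 0.24), as did T19D12.4 (0.92 and -0.80), a ratio of -1.72 (SE 0.21). The other way went scl-2, of the SCP-like secreted protein family (-2.57 in global and 3.26 in hypodermal depletion), a ratio of 5.83 (SE 0.45), and dct-16 (-1.35 and 1.33), a ratio of 2.68 (SE 0.26). So did the cathepsin L gene cpl-1 (-1.17 and 1.03), a ratio of 2.20 (SE 0.25), the aspartyl protease gene asp-13 (-1.93 and 1.19), a ratio of 3.12 (SE 0.37), and mua-3, which encodes a protein linking epidermis to cuticle (-0.85 and 0.91), a ratio of 1.76 (SE 0.23).

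For the intestinal and immune genes that differed, the prediction on genome segments was written before its result was seen, and the tests of cell number and of the driver were chosen after it. Fewer intestinal cells in global depletion, as the only cause, would lower the markers by a like amount. Yet their log2 differences had an interquartile range of 1.46 and 1 of 19 markers was called in the other direction. Their median was 0.55 higher in hypodermal depletion, with 8 called higher. Fewer cells as part of the cause therefore cannot be told apart from changes of single genes. A genome segment that differs between the strains, as the main source of the calls, would crowd them on its chromosome. Yet the chromosome with most, V, held 23.4% of the 355 calls and 17.9% of tested genes. A segment of any size that gives part of the calls, such as one holding the neighbours pud-3 and pud-4, stays possible. Each driver of TIR1 stands in 1 strain, with 0 further groups for either driver, so an effect of the driver and one of the strain cannot be told apart here.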

How the results depend on the processing

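Of the named genes called, those called under every alternative in which they were tested numbered 45 of 81 (global against 24 h controls), 26 of 57 (hypodermal against 24 h controls), 32 of 64 (hypodermal against global), 12 of 48 (24 h against 18 h controls), 58 of 83 (global against 18 h controls) and 47 of 81 (hypodermal against 18 h controls). A gene that an alternative could not test was not counted as lost there. Of the 678 genes called in global depletion against 24 h controls, thinned libraries could test 520 and the filter on mean CPM 412. For the values of named genes under an alternative, 9727 kept their side of the threshold, 927 lost their call, 7 gained one and 2 reversed. A turn of direction was counted only for a gene called in the main fit or under the alternative. For lists, 1694 were the same, 217 weaker and 2 reversed, and of 149 counts of called genes 111 stayed within 1.5-fold of the count reported.

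A minimum fold of 1.5 lowered the counts, by its construction, to 286 (global against 24 h controls), 159 (hypodermal against 24 h controls), 142 (hypodermal against global), 74 (24 h against 18 h controls), 591 (global against 18 h controls) and 464 (hypodermal against 18 h controls). Thinning to the shallowest total, added after seeing the data, gave 356, 164, 134, 156, 750 and 681 in that order with fewer counts per library. For 24 h against 18 h controls, limma-voom called 144 genes, a fit of these groups by themselves 92 with fewer samples, and no filter 435. No filter gave 1626 for hypodermal depletion against 18 h controls. For hypodermal depletion against 24 h controls unlisted counts as 0 gave 250 and the filter on mean CPM 245, both added after seeing the data. For these the cause was not tested.

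Leaving out 1 library at a time gave 348 (without global replicate 2) to 761 (without 18 h control replicate 1) for global against 24 h controls, 244 (24 h control replicate 1) to 463 (18 h control replicate 1) for hypodermal against 24 h controls, and 156 (global replicate 1) to 427 (24 h control replicate 1) for hypodermal against global. It gave 76 (24 h control replicate 2) to 241 (hypodermal replicate 1) for 24 h against 18 h controls, 657 (18 h control replicate 1) to 1262 (24 h control replicate 2) for global against 18 h controls and 507 (18 h control replicate 1) to 1118 (24 h control replicate 1) for hypodermal against 18 h controls. Groups of 2 left with 1 library hold fewer samples. Each of these fits was also filtered and adjusted anew, so the genes tested changed from 8026. They numbered 9154 to 9236 without a control library, 8424 to 8473 without a global and 7338 to 7873 without a hypodermal library. A call lost near the threshold may therefore come from the changed fit and not from the values of the library left out.

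A replicate term gave 269 for hypodermal depletion against 24 h controls and 211 between the depletions. It ended the calls of the pharynx list in hypodermal depletion against 24 h controls (adjusted p = 0.0894) and the neuronal list between the depletions (0.224). Against 18 h controls it ended those of the replication, lysozyme and neuronal lists in hypodermal depletion (0.0613, 0.0613 and 0.111). It also added calls: intestine (0.00344), C-type lectins (0.00835) and daf-16 targets (0.0221), lower in hypodermal depletion against 24 h controls, and basement membrane (0.0221) and glycolysis (0.0465), higher in hypodermal than in global depletion. It added glycolysis (0.0371) and neurons (0.0427), lower at 24 h than at 18 h. Against 18 h controls it added C-type lectins (0.0264), p38 and bZIP genes (0.0492), fatty acid oxidation (0.0462) and glycolysis (0.0491), lower, and basement membrane (0.00838), higher, in hypodermal depletion. Whether replicate numbers pair the samples cannot be told. Over 12 pairs of the same number, residuals correlated from -0.286 to 0.31, and for other pairs from -0.31 to 0.301. In groups of 2 the residuals mirror each other, so these ranges are alike by construction. Of the 12 pairs 2 lay above 0.1, both between the depletions (0.31 for replicate 1 and 0.249 for replicate 2). The lowest was between 24 h control and hypodermal replicate 1.

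The correlation between the depletions was 0.316 without a shared control (hypodermal depletion against the 18 h controls), 0.854 and 0.735 with unlisted counts as 0 and 2, 0.699 thinned and 0.695 to 0.824 with 1 library left out. Their covariance was 1.713 and 0.529 with unlisted counts as 0 and 2, 0.48 thinned and 0.62 to 1.165 with 1 library left out. The simulated sets of unchanged groups were run with unlisted counts as 1 and without the 18 h controls only. The positions of hypodermal and global depletion were 0.941 and 0.874 with a log2 ratio of at least 2, 1.21 and 1.141 at 50 CPM or more, 1.123 and 1.014 without collagens, 1.064 and 0.964 with unlisted counts as 0.5, and 1.071 and 0.986 with 2. Leaving out a library gave 1.021 to 1.065 and 0.952 to 0.966. The cause was not tested.

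With no filter the direction turned for the tricarboxylic acid list in global depletion against 18 h controls (adjusted p = 0.705) and for body wall muscle in hypodermal depletion against 18 h controls (0.752). For global against 24 h controls the estimate of col-165 turned to -0.401 with pooled controls, by construction, since it was high at 18 h, and that of abu-8 to 0.64 without 24 h control replicate 1 (-3.259 without replicate 2). The shallow controls limit what can be seen: with the TMM factors 3 counts stood for 16.469 CPM on average at 18 h and 7.795 at 24 h, against 2.447 and 2.421 in hypodermal and global depletion.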

Other observations

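Some groups not called as sets in either depletion against the 24 h controls changed in a few members. The linker histone gene his-24 fell in both depletions against the 24 h controls (log2 fold change -1.80, SE 0.26, in global and -1.73, SE 0.23, in hypodermal depletion by edgeR), while 3 and 2 of 25 histone genes fell (3 in each over the list alone, camera adjusted p = 0.0884 and 0.128). Of 39 glutathione-related genes 3 rose and 5 fell in global depletion (5 and 5 over the list alone, adjusted p = 0.666) and 3 rose and 2 fell in hypodermal depletion (8 and 2 over the list alone, 0.0517). Of 41 UDP-glucuronosyltransferase genes 3 rose in global depletion (3 over the list alone, 0.158), with ugt-44 at 2.34 (SE 0.44), and 2 rose in hypodermal depletion (6 higher and 2 lower over the list alone, 0.0526). Of 42 C-type lectin genes 5 rose and 6 fell in global depletion (5 and 7 over the list alone, 0.161), with clec-42 at -2.52 (SE 0.42), and 1 rose and 4 fell in hypodermal depletion (1 and 5 over the list alone, 0.128), with clec-1 at -1.77 (SE 0.30).

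For the cuticle collagens lower in both depletions, each test was chosen after the result was seen. Of these 28 collagens, chosen as lower at full depth, 19 could be tested after thinning. Their median log2 fold change was then -2.81 in global and -2.596 in hypodermal depletion (-4.80 and -4.78 for the same 19 before, with lower floors for unlisted counts). At fewer counts 14 and 17 were still called lower. The fall of these 19 as a set thus did not rest on unequal floors alone. Thinning keeps the expected share of each gene in its library, so it cannot test other effects of depth. The other 9 collagens were too low to test after thinning, so for them depth and depletion cannot be told apart. Loss of hypodermal cells as the whole cause would lower the hypodermal markers as well. The median of the markers lay at least 3.41 (log2) above that of these 28, which were chosen as lower. Above that of all 64 collagens tested it lay by 0.89 in global and 1.35 in hypodermal depletion. The gap of 0.89 fell short of the limit set for this test. Loss of some hypodermal cells as part of the cause therefore cannot be told apart from changes of single genes. A stage between the controls cannot be told apart from an effect of depletion, although 19 of 28 were lower than the 18 h controls too in both depletions, since collagens can cycle with the molt and no time in between was held, and nor can a later phase of the molt, with 0 later control groups held.

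For the genes higher in both depletions, the test of IAA as the only cause was written before its result, and the other tests were chosen after. Of these 81 genes, chosen as higher at full depth, 67 could be tested after thinning. Their median log2 fold change was then 1.58 in global and 1.26 in hypodermal depletion (1.59 and 1.285 for the same 67 before). At fewer counts 49 and 29 were still called higher. The rise of these 67 as a set thus did not rest on unequal floors alone. Thinning keeps the expected share of each gene in its library, so it cannot test other effects of depth. For the other 14, too low to test after thinning, depth and depletion cannot be told apart. IAA at the same dose as the only cause, acting alike in both strains, could not explain the 13 that differed between the depletions. Of these 13, 12 were higher in global depletion. Whether the strains respond differently to IAA was not tested. For the 68 that did not differ, IAA as the only cause cannot be told apart from an effect of depletion. With 0 control libraries that received IAA, an effect of IAA or TIR1 together with the driver cannot be told apart either.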
